A study of Mus musculus with 2 samples.

How the data were processed

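H3K27ac was profiled by chromatin immunoprecipitation and sequencing in embryonic day 12.5 mouse heart (strain B6NCrl, male and female embryos pooled), in 2 biological replicates from separate tissue samples, with fragments of 300 to 500 per the labels (no unit given). The deposited files were 4 peak lists in narrowPeak form on mm10. Of these, 1 was called on each replicate with 1 control, 1 on both replicates together with their controls (the pooled list), and 1, the replicated list, was derived from the other 3. The peak caller, the aligner, the scaling of the control and the overlap rule behind the replicated list were not given in the sources used here. The fold of a peak is a ratio of enrichment over the control that the authors computed. The deposited p-values and q-values are in units of −log10 p and −log10 q, and the smallest −log10 p in the lists was 2.00 to 2.01, so the authors kept peaks with p up to about 0.01. The deposited summit is an offset in bp from the start of the peak. Folds were used for ranks and values within a list only, since their scale may differ between lists.

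Reads and counts were not used here, so the depth of each replicate is unknown and precision is limited to the number of peaks, 102386 and 108636. Of a share of peaks, 95% Wilson intervals were computed, and they cover counting error only. Peaks on unplaced scaffolds (5 to 8 per list) were left out where annotation was needed. Positions of genes and transcription starts came from GENCODE M21 on GRCm38.p6, and those of peaks were turned from 0-based to 1-based. All 419 members of the gene lists matched 1 protein-coding gene of the annotation.

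Both samples formed a single group, so no test between groups, no pairing and no split of samples was possible, and the comparisons were set by the lists themselves. Overlap between the replicates was counted with at least 1 bp shared, in each direction and by 10% steps of the fold, against 100 placements of the peaks at random within their chromosomes outside assembly gaps (one-sided permutation test; the smallest p is 0.0099). The same placements gave the chance level for peaks within 1 kb of a start. For each of 23 gene lists, the share of members with a replicated peak within 1 kb of any annotated start was tested against all other protein-coding genes by Fisher's exact test, two-sided. Because any annotated start counts, a start peak can lie inside a gene, away from its 5′ end. The median of the bases under peaks within 50 kb of the 5′ end was compared with 10000 random lists of equal size, drawn with replacement (two-sided permutation test; the smallest p is 0.0002). P-values were adjusted by the method of Benjamini and Hochberg over the lists, at 0.05. Genes that lie near each other share peaks and are not independent.

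Peaks farther than 1 kb from a start were joined where under 12.5 kb apart, and the clusters were ranked by their bases under peaks. Those past the point where the ranked curve, scaled to its range, has a slope of 1 were called long, a rule set after the data were seen. Genes of each list nearest to a long cluster were counted among genes nearest to any cluster (Fisher's exact test). For the 39415 summits farther than 2.5 kb from a start, windows of 301 bp were searched on both strands for 25 consensus sequences fixed before the data were examined. As many windows of equal GC share outside all peaks were the background (Fisher's exact test, adjusted over the 25). Each consensus was also searched with its letters in shuffled order, up to 20 times, as a control. Peak density of X was set beside the 19 autosomes without a test.

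The named genes were chosen by a rule fixed before the data were examined. It took the 3 members of each list with the largest fold of their start peak, up to 3 members without one in alphabetical order, the 10 strongest distal peaks, the 10 longest clusters, and any member of the sarcomere and cardiac factor lists by its covered bases. Other genes are named as chosen after their values were seen, and genes nearest to long clusters are examples from the counts. Alternatives were a stricter q of 0.01 or fold of 3, other overlap rules, autosomes alone, each replicate alone, other distances and windows, other random lists, distal peaks only, other joining distances and rankings, and other motif windows and backgrounds. A further 5 alternatives were added after the data were seen: a background matched on repeats, the erythroid list without globins, bases away from starts of other genes, X peaks per gene, and the 500 and 1000 longest clusters.

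The steps were tested on simulated data. Of simulated replicate 1 peaks, 60.4% were found overlapped where 60% had been shared, 3 of 3 lists made higher and 2 of 2 made lower were called by share, and 1 of 18 other lists was called. By covered bases, 3 of 3 lists made higher were called, and so were 3 others whose genes lie in clusters (anterior Hox, posterior Hox and erythroid). A density of X kept at 0.25 was found as 0.228. All 4 planted sequences were called, and 1 of 21 not planted was called, with a ratio of 1.08. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used. The text files that came with the peak lists were read for the origin of the lists, and their contents were not analysed here.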

Results

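Acetylation of lysine 27 on histone H3 (H3K27ac), a mark of active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in hearts of mouse embryos at embryonic day 12.5. The samples formed 1 group of 2 biological replicates, each from tissue of strain B6NCrl pooled over male and female embryos. Replicate 1 had 2 technical replicates and replicate 2 had 1. The deposited peak lists held 102386 peaks for replicate 1, 108636 for replicate 2, 123549 for both replicates together (the pooled list) and 65353 in a replicated list. Read numbers were not given in the sources used here, so the depth behind the peaks was unknown. The fold of each peak was the authors' enrichment over control and was ranked within a list only; where folds of several lists stand together they are side by side, not compared. Positions refer to mm10, count from 1 and include both ends.

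Strong H3K27ac peaks of the embryonic heart were found in both replicates, whereas weak ones were often found in only 1. Of the replicate 1 peaks, 68696 of 102386 (67.1%, 95% Wilson interval 66.8% to 67.4%) shared at least 1 bp with a replicate 2 peak. Of the replicate 2 peaks, 62598 of 108636 (57.6%, interval 57.3% to 57.9%) shared a base with a replicate 1 peak. In the strongest 10% by fold, 100% of the replicate 1 peaks and 99.9% of the replicate 2 peaks were overlapped by the other list. In the weakest 10% these shares were 44.7% and 32.0%. Strong peaks were also wider, with a median width of 1203 and 1395 bp in the strongest 10% and 196 and 205 bp in the weakest. A wide peak can share a base more easily, and fold and width were not separated. Of the 10000 strongest peaks of replicate 1, 79.6% overlapped the 10000 strongest of replicate 2, and 76.2% did so in the other direction. Random placement of the same peaks within their chromosomes gave 3.92% ± 0.0614 (SD of 100 placements) for replicate 1 and 3.61% ± 0.0554 for replicate 2, so the observed shares were 17.1 and 16.0 times those of chance (one-sided permutation p = 0.0099 for each, the smallest that 100 placements allow). The intervals cover counting error only, and neighbouring peaks are not independent. With a reciprocal overlap of 50% required, the shares were 37.6% and 35.4%.

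**Figure D1:**
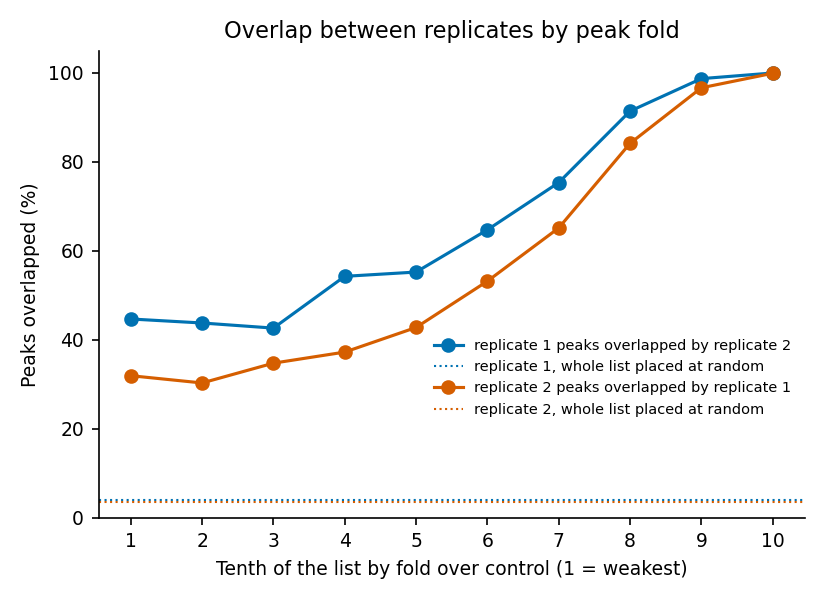
Share of the peaks of each replicate (vertical axis, percent) that the other replicate overlapped, by 10% step of the peaks ranked on their own fold (horizontal axis, weakest to strongest). Replicate 1 goes from 44.7% in the weakest step to 100% in the strongest, and replicate 2 from 32.0% to 99.9%.

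The replicated list was a subset of the pooled list, and it held the stronger and wider peaks of embryonic heart. All 65353 replicated peaks had an identical line in the pooled list, of which they made up 52.9% (interval 52.6% to 53.2%). Their median fold was 4.46 and their median width 562 bp, against 2.78 and 198 bp for the 58196 pooled peaks left out. Of those left out, 23404 overlapped a replicate 2 peak alone, 15546 a replicate 1 peak alone, 643 peaks of both, and 18603 neither. Each of the 54831 pooled peaks that shared at least 50% of either peak's length with a peak in both replicates was in the replicated list. A further 10522 replicated peaks did not meet that rule, and 10134 shared no base with a peak of at least 1 replicate, so the rule behind the list was not recovered in full. Peaks of the replicated list covered 54.5 Mb, or 2.06% of the genome, and they were used for the comparisons that follow.

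H3K27ac in the heart lay at gene starts far more often than chance, and most of the remaining peaks lay in introns. Of 65348 replicated peaks on the main chromosomes, 20239 (30.97%) lay within 1 kb of an annotated transcription start. Peaks at starts had a median fold of 6.22 and a median width of 745 bp, against 4.14 and 507 bp elsewhere. By their summits, 28.4% of the peaks lay at starts, 4.05% in exons, 46.4% in introns and 21.1% between genes. Random placement of peak midpoints gave 6.38%, 3.39%, 40.3% and 49.9% for the same classes. Beyond the starts, 30.1% of the summits lay 10 to 50 kb from the nearest one, 4.61% lay 50 to 100 kb away and 1.55% farther. Random placement put 8.58% ± 0.0936 (SD of 100 placements) of peaks within 1 kb of a start, so the observed share was 3.61 times that of chance (one-sided permutation p = 0.0099). In the lists of the replicates alone, 26.0% and 24.8% of the peaks lay there.

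The contractile apparatus and the cardiac transcription factors had the highest medians of bases under H3K27ac peaks among the 23 gene lists, which were fixed before the data were examined. All 22 sarcomere genes had a replicated peak within 1 kb of an annotated start, in each replicate alone as well. The strongest start peaks lay at Myom1, which links thick filaments at the M band, with a fold of 47.6 (40.3 in replicate 1, 36.5 in replicate 2), at Tnni1, the slow troponin I of embryonic heart, with 35.7 (28.6 and 31.6), and at Myl4, the atrial light chain of myosin, with 28.7 (26.5 and 22.7). The Myom1 peak spanned 17:71001151-71004699 at the 5′ end of the gene. The Tnni1 peak (1:135798298-135801845) and the Myl4 peak (11:104576057-104580990) lay at annotated starts inside their genes. Within 50 kb of the 5′ end, peaks covered a median of 22.1 kb per sarcomere gene (19.1 kb in replicate 1, 21.1 kb in replicate 2), against 2.40 kb for all protein-coding genes. The cardiac myosin heavy chains Myh6 and Myh7 had 58.2 and 51.9 kb, the Z disc genes Actn2 and Ldb3 had 40.5 and 36.1 kb, and Nebl had 0.41 kb. The start peak of Nebl (2:17459729-17460810, fold 16.6) lay inside the gene, more than 50 kb from its 5′ end, so the window did not count it.

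All 24 cardiac transcription factors had a start peak too, in each replicate alone as well. Mef2a, a factor of muscle gene transcription, had a fold of 36.2 (28.5 and 33.3) at 7:67371461-67375408. Gata4, a zinc finger factor needed for heart formation, had 31.9 (26.2 and 34.9) at 14:63266749-63272988, and Tead1, a DNA-binding factor of the Hippo pathway, had 29.1 (26.2 and 27.1) at 7:112677677-112681379. The list had a median of 16.0 kb covered per gene (14.4 and 13.8 kb). Gata4 led with 45.4 kb, followed by Tbx5 with 42.1, Nkx2-5 with 40.4 and Gata6 with 37.5 kb, all early regulators of the heart. Isl1, a gene of progenitors of the second heart field, had 0.41 kb. Smyd1 had 0.85 kb, but its start peak (6:71259125-71263708, fold 15.3) lay inside the gene. That peak was more than 50 kb from the 5′ end, so the window did not count it. The share of genes with a start peak was above the 52.4% of all 21938 protein-coding genes (Fisher's exact test, two-sided; raw p = 7.3e-07 and adjusted p = 5.6e-06 for the sarcomere, raw p = 2.0e-07 and adjusted p = 2.3e-06 for the factors). The covered bases of both lists lay above those of all 10000 random lists (permutation p = 0.0002, the smallest possible; adjusted p = 0.00115). Of the 24 factors, 4 also stood in another list, as did 5 of the 414 genes in all.

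**Figure D2:**
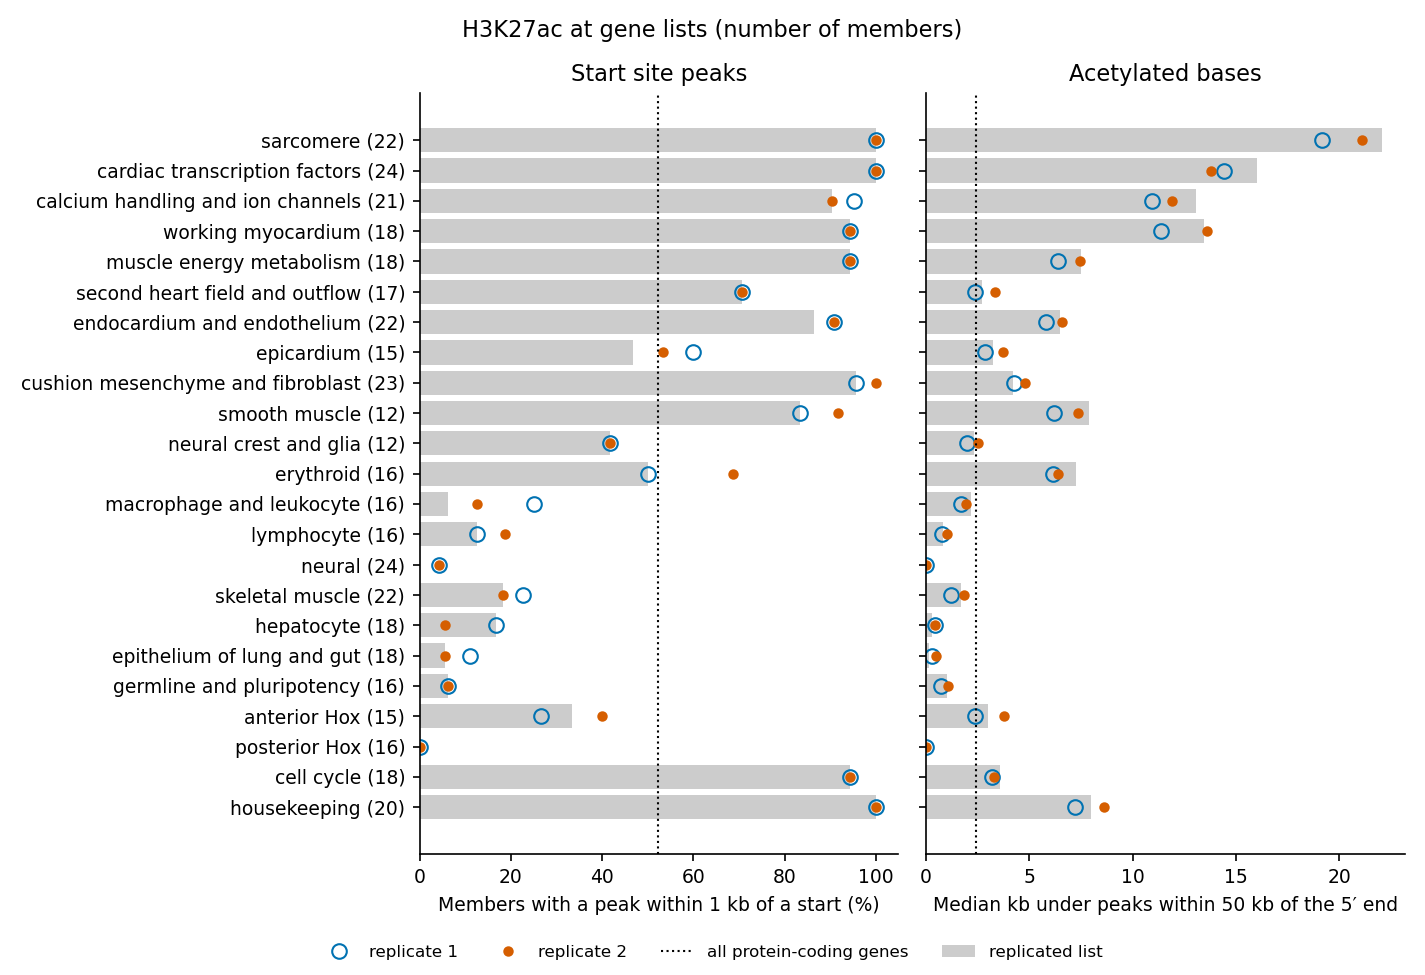
For each gene list, the percent of members with a peak within 1 kb of a start (left) and the median kb under peaks within 50 kb of the 5′ end (right), as bars for the replicated list and points for each replicate; dotted lines give all protein-coding genes (52.4% and 2.40 kb). The sarcomere list reached 22.1 kb, the cardiac transcription factors 16.0 kb, and the neural and posterior Hox lists 0.0 kb.

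Genes of the beating and working myocardium were acetylated as well. Of the calcium handling and ion channel genes, 19 of 21 had a start peak, with the largest folds at the calcium pump Atp2a2 (29.1), the calcium channel Cacna1c (29.1) and the potassium channel Kcnh2 (27.02). The channel Hcn1 and the pump regulator Sln had none. Of the working myocardium genes, 17 of 18 had a start peak, led by Popdc2 (29.8), Synpo2l (25.1) and Xirp1 (24.1), and Xirp2 had none. Of the genes of muscle energy metabolism, 17 of 18 had one, among them Ppargc1a, a coactivator of mitochondrial genes (21.8), Acadm, an enzyme of fatty acid oxidation (20.8), and myoglobin, Mb (19.2), and Ppara had none. These lists had medians of 13.1, 13.5 and 7.498 kb covered per gene. Their shares with a start peak were higher than among other genes (adjusted p by Fisher's exact test 0.000512, 0.000352 and 0.000352), and so were their covered bases (adjusted permutation p 0.00115, 0.00115 and 0.013). With the annotated 5′ end as the only start, the call for the share of calcium handling and ion channel genes (71.4%) was lost. The call for covered bases of energy metabolism was lost in a window of 100 kb (adjusted permutation p = 0.0705), among members with a start peak (0.146) and with distal peaks only (1.44 kb, 0.289).

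Lists of other cell types of the heart were each compared with all genes, and not with each other. Endocardial and endothelial genes had start peaks at 19 of 22 members, with folds of 15.1 at the natriuretic peptide receptor Npr3, 12.7 at the adhesion molecule Pecam1 and 10.3 at the factor Tal1, and a median of 6.47 kb covered. Cldn5, Flt4 and Sox17 had no start peak. Cushion mesenchyme and fibroblast genes had start peaks at 22 of 23 members, led by the matrix genes Vcan (20.9) and Col3a1 (12.8) and the growth factor Tgfb2 (12.4), with Msx1 alone lacking one, and a median of 4.20 kb. Smooth muscle genes had 10 of 12, with Des (20.6), Smtn (15.1) and Synpo2 (13.0) strongest, Kcnmb1 and Myh11 without, and a median of 7.87 kb. Second heart field and outflow genes had 12 of 17, with Foxc1 (29.9), Hand2 (20.3) and Mef2c (19.1) strongest and Fgf10, Fgf8 and Six1 among those without. Epicardial genes had 7 of 15, with Tcf21 (9.88), Tbx18 (8.08) and Bnc2 (5.12) strongest and Aldh1a1, Aldh1a2 and Krt18 among those without. Neural crest and glial genes had 5 of 12, with Ets1 (15.9), Ednrb (11.3) and Mpz (8.22) strongest and Fabp7, Foxd3 and Phox2b among those without. Of the genes named here and above as lacking a replicated start peak, Sln and Cldn5 had one in the list of replicate 1, and Sox17, Msx1 and Kcnmb1 in that of replicate 2.

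Of these lists, the endocardial one passed both tests (Fisher's exact test, adjusted p = 0.00179; covered bases, adjusted permutation p = 0.0215). The cushion list passed for the share with a start peak (adjusted exact p = 3.2e-05) but not for covered bases (adjusted permutation p = 0.25). Smooth muscle passed for covered bases (adjusted permutation p = 0.0221) but not for the share (adjusted exact p = 0.0524). The most covered bases among its members were those of Des (30.96 kb) and Myocd (27.98 kb), and Myocd also stands in the cardiac factor list. Myh11 had 0.52 kb and Kcnmb1 0.00 kb. The second heart field, epicardial and neural crest lists passed neither, with adjusted exact p of 0.182, 0.834 and 0.622 and medians of 2.73, 3.24 and 2.31 kb (adjusted permutation p of 0.884, 0.677 and 0.908). The endocardial and smooth muscle calls for covered bases were lost in a window of 100 kb (adjusted permutation p of 0.0705 and 0.0741) and among members with a start peak (0.146 each), and that of smooth muscle also with distal peaks only (0.873 kb, 0.742) and with bases away from starts of other genes (3.77 kb, 0.104). The cushion list was called in a window of 20 kb (3.75 kb, adjusted permutation p = 0.00172), against lists matched on gene density (0.0368) and with bases away from starts of other genes (0.0143), and the share of smooth muscle genes with a start peak was called in replicate 2 alone (91.7%).

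Genes of the neural, Hox, epithelial, hepatocyte, germline, macrophage, lymphocyte and skeletal muscle lists mostly lacked H3K27ac peaks at their starts. No peak of the replicated list lay at a start of any of the 24 neural genes, which include the neuronal regulators Ascl1, Dlx1 and Dlx2, or of the 16 posterior Hox genes, among them Hoxa10, Hoxa11 and Hoxa13, which pattern the posterior body. A start peak was present at 1 of 18 lung and gut epithelial genes (Trp63, 3.81), 3 of 18 hepatocyte genes (Trf, 5.74; Foxa3, 4.61; Ttr, 3.51) and 1 of 16 germline genes (Dazl, 3.78). Among blood lists, it was present at 1 of 16 macrophage genes (Cd68, 3.29) and 2 of 16 lymphocyte genes (Lck, 3.95, and Cd3d, 3.03). Of the skeletal muscle genes 4 of 22 had one, namely the light chain gene Mylpf (11.9), the fast troponins Tnni2 (6.98) and Tnnt3 (6.40) and Actn3 (4.26), whereas Acta1, Cacna1s and Chrna1 were among those without. Anterior Hox genes had start peaks at 5 of 15 members, led by Hoxa1 (7.28), Hoxb2 (5.93) and Hoxb3 (5.22). The lists of replicate 1 and replicate 2 gave 4 and 2 macrophage genes, 2 and 3 lymphocyte genes, 3 and 1 hepatocyte genes, 2 and 1 epithelial genes, 5 and 4 skeletal muscle genes and 4 and 6 anterior Hox genes with a start peak. Foxa3 and Ttr had none in replicate 2, Chrna1 had one in replicate 1, and of the neural genes Pax6 had one in replicate 1 and Syt1 in replicate 2.

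The shares were lower than among other genes for 8 lists (adjusted p by Fisher's exact test): neural (4.3e-07), posterior Hox (3.2e-05), lung and gut epithelium (0.000137), macrophage (0.000352), germline (0.000352), lymphocyte (0.00252), skeletal muscle (0.00283) and hepatocyte (0.00448). The anterior Hox list did not pass (adjusted exact p = 0.225). Covered bases were lower for the neural, posterior Hox and epithelial lists, with medians of 0.0, 0.0 and 0.163 kb (adjusted permutation p of 0.0138, 0.0349 and 0.0314), and did not pass for the macrophage, lymphocyte, skeletal muscle, hepatocyte, germline and anterior Hox lists, with medians of 2.19, 0.803, 1.69, 0.311, 1.03 and 2.98 kb (adjusted permutation p of 0.887, 0.23, 0.62, 0.0584, 0.311 and 0.785). In a window of 20 kb none of the 3 lower calls for covered bases held (adjusted permutation p of 0.186, 0.212 and 0.208), all 3 medians being 0.0 kb, the lowest possible value; the same held with distal peaks only. The epithelial call was also lost in a window of 100 kb (2.46 kb, adjusted permutation p = 0.289), in replicate 2 alone (0.467 kb, 0.0556) and with bases away from starts of other genes (0.163 kb, 0.106), as was that of posterior Hox in the last setting (0.0 kb, 0.0931). The hepatocyte list was called lower against lists matched on gene density (adjusted permutation p = 0.0368), and the share of anterior Hox genes was called lower with the 5′ end as the only start (20%).

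Erythroid, cell cycle and housekeeping genes stood apart from these. Erythroid genes had start peaks at 8 of 16 members (adjusted exact p = 1.0), with the anion exchanger Slc4a1 (6.92), the factor Nfe2 (6.23) and the receptor Epor (5.53) strongest and Alas2, Gata1 and Gypa among those without. In replicate 2 alone 11 had one, Alas2 among them, and in replicate 1 alone 8. Their median of 7.27 kb covered was above random lists (adjusted permutation p = 0.0195), but it was 3.27 kb without the globin genes (adjusted permutation p = 0.77), and the call was lost in windows of 20 kb (0.0722) and 100 kb (0.447) and against lists matched on gene density (0.188). Near-identical copies of the globin genes make their peaks uncertain, and these genes share bases within each cluster. On simulated data the same test also called 3 lists in which no bases had been added, the erythroid list among them. Cell cycle genes had start peaks at 17 of 18 members, led by Cdk2 (24.1), Ccnd3 (22.7) and Mcm7 (17.8), with Mcm3 lacking one. Their median of 3.57 kb did not pass against random lists (adjusted permutation p = 0.527), whereas the share did (adjusted exact p = 0.000352). All 20 housekeeping genes had a start peak (adjusted exact p = 1.6e-05), led by the cytoskeletal actin Actb with 51.5 (31.1 and 47.5), Ywhaz (37.0) and Ubc (31.3), and a median of 8.004 kb (adjusted permutation p = 0.00552). Among list members with a start peak, compared with random lists of such genes, the covered bases of the housekeeping list did not pass (adjusted permutation p = 0.113), nor did they with distal peaks only (1.71 kb, 0.156).

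At the locus of the cardiac myosin heavy chains, peaks covered the 5′ ends of both genes and sequence upstream of them. Myh6, the alpha heavy chain (14:54941921-54966927, minus strand), had a start peak of fold 15.8 at 14:54963558-54973849. Myh7, the beta heavy chain of embryonic ventricle (14:54970684-54994626, minus strand), had one of fold 27.6 at 14:54982601-54996920. A peak of fold 29.2 at 14:55001923-55006332 lay upstream of Myh7 and was singled out after its value was seen. The region 14:54921921-55014626 held 36 replicated peaks, 48 of replicate 1 and 51 of replicate 2. The windows of the 2 genes overlap, so their covered bases are not independent.

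**Figure D3:**
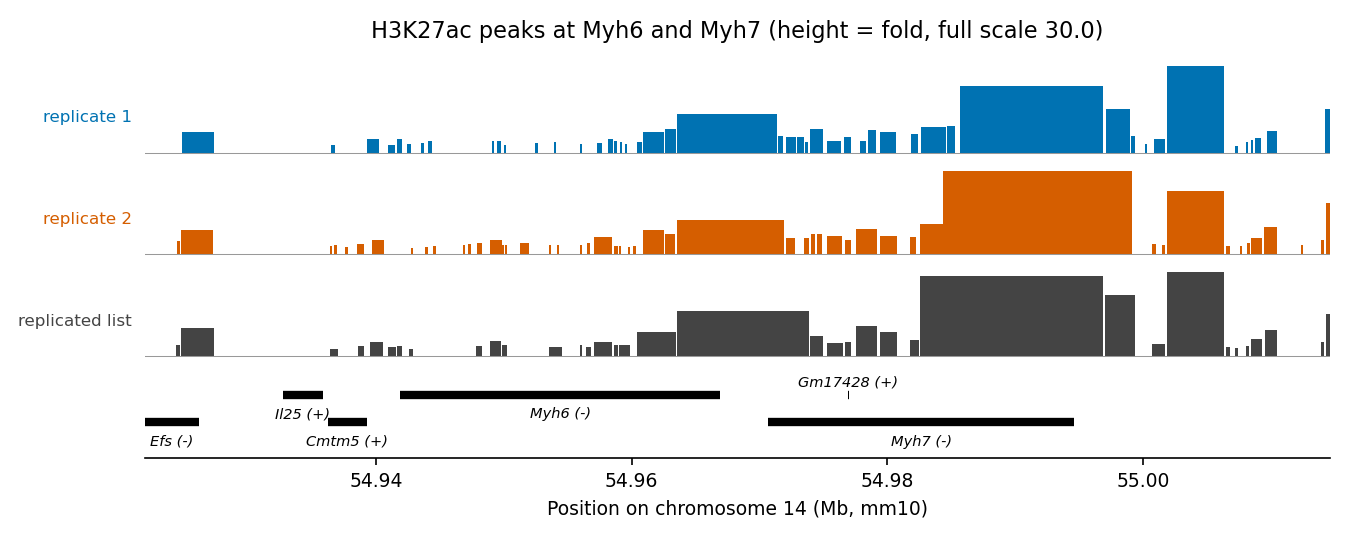
Peaks at Myh6 and Myh7 on chromosome 14 (horizontal axis, Mb, mm10) in replicate 1, replicate 2 and the replicated list; each box spans a peak and its height is the fold of the whole peak within that list. Genes are drawn below with their strand, and the widest boxes lie at the starts of Myh7 (fold 27.6) and Myh6 (fold 15.8).

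Cardiac transcription factors were nearest to long clusters of distal H3K27ac peaks more often than other genes were. None of the 10 longest clusters was nearest to a listed factor. Joining the 45109 peaks away from starts where they lay under 12.5 kb apart gave 16801 clusters, of which 842 were long (at least 6.57 kb under peaks, median 10.04 kb) and held 33.4% of the covered bases. The longest lay in Msi2, an RNA-binding protein gene, at 11:88440780-88676619 with 91 peaks and 94.9 kb under peaks (78.8 kb in replicate 1, 91.6 kb in replicate 2). It was followed by clusters nearest to Wasf2 (66.3 kb), Rbpms (65.2), Smad6 (63.2), Lrrfip1 (51.8), Cgnl1 (50.8), Igf2r (49.9), Parva (48.7, lying in Mical2), Tspan9 (48.1) and Rbm20, a splicing regulator of sarcomere genes (48.1). Of these 10 nearest genes, 4 were also nearest to 1 of the 10 top clusters with a joining distance of 5 kb, 6 when ranked by summed fold times width, 6 with start peaks kept and 7 in each replicate alone. Among genes nearest to any cluster, 14 of 22 cardiac transcription factors were nearest to a long one, Gata4, Gata6, Nkx2-5, Tbx5 and Tbx20 among them. So were 10 of 19 calcium handling and ion channel genes, including Atp2a2, Ryr2 and Pln, and 8 of 20 sarcomere genes, including Actn2, Myl2 and Tnnt2. Of all 8698 such genes 742 (8.53%) were nearest to a long cluster.

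The excess of long clusters held for these 3 lists (Fisher's exact test, two-sided, over 23 lists): adjusted p = 3.7e-09 for the factors, 1.0e-05 for calcium handling and ion channels and 0.00103 for the sarcomere. Working myocardium had 5 of 16 (adjusted exact p = 0.0505) and passed in 7 of 8 alternatives, all but the ranking by summed fold times width. Muscle energy metabolism had 3 of 11 (adjusted exact p = 0.28), cushion mesenchyme 4 of 23 (0.418) and endocardium 3 of 20 (0.503). The strongest single distal peak lay in an intron of Mb at 15:77035377-77041103, with a fold of 41.7 (27.5 and 34.3), and the nearest 5′ end was that of Apol6. The next lay in Pkig (35.2) and in introns of Ccnd3 (34.5) and Hipk3 (33.9), in an intron of Myh9 with Apol8 nearest (33.3), near Tex44 (31.6), in Tns1 (31.5), near Plekhg2 (31.5), in Dnmt3a (31.2) and near Actg1 (31.2). With clusters ranked by summed fold times width, 2 lists passed and the sarcomere call was lost. The length that set the long class was chosen from the ranked lengths, and nearness to a 5′ end does not show which gene a cluster acts on. Genes were not matched on length or on the space around them, which affects how many clusters they can be nearest to.

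Distal H3K27ac peaks were richer in some heart factor sequences, such as that of TEAD, than genomic windows of equal GC share. Other such sequences, those of the T-box and of HAND factors, had fewer matches. Of 39415 distal peaks, 6.71% had a match of the TEAD consensus within 150 bp of the summit, against 4.68% of background windows, a ratio of 1.43. The ratio was 1.67 for the ESRR consensus, bound by receptors that act on mitochondrial genes, 1.297 for MEF2, 1.27 for NKX2, 1.27 for FOX, 1.26 for the E-box CAGCTG, 1.25 for RUNX, 1.18 for AP1, 1.14 for the TGTCA element of MEIS factors, 1.07 for SOX and 1.05 for GATA. Matches were fewer than in the background for CTCF, which binds insulators (0.396), for POU factors (0.823), for the T-box (0.839) and for the E-box CATCTG of HAND factors (0.936). The other 10 of the 25 sequences did not pass the test, among them SRF (0.922) and NFI (2.33, on 14 peaks and 6 background windows). NFI passed in each replicate alone (4.14 in replicate 1 and 4.25 in replicate 2). With the background also matched on repeat bases, its ratio in the replicated list was 1.0. In the 10 strongest distal peaks, the summit window in Ccnd3 held a GATA match (TGATAG, 17:47522203-47522208), and that in Hipk3 held a GATA match (TGATAA, 2:104467139-104467144) and a TEAD match (GCATTCCT, 2:104467104-104467111). These windows were searched only for the GATA, MEF2, T-box, NKX2, TEAD, ESRR, SRF and FOX sequences. GATA matches stood in 38.2% of all distal peaks and 36.4% of background windows, so these matches are examples and show no enrichment.

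By Fisher's exact test over 25 sequences, adjusted p was 8.4e-34 for TEAD, 4.6e-54 for CAGCTG, 1.5e-11 for ESRR, 5.0e-09 for MEF2, 2.7e-09 for NKX2 and 1.5e-07 for GATA. The ratios of TEAD, MEF2, NKX2 and RUNX exceeded those of all 20 shuffled forms of the same consensus (highest 1.204, 1.14, 1.17 and 1.21), whereas those of the other sequences called, such as GATA (1.08) and CAGCTG (1.26), lay within the range of theirs. Against flanking windows, which had fewer G and C bases, the ratios of GATA, MEF2, FOX and RUNX were below 1 (0.868, 0.570, 0.893 and 0.956) and that of CATCTG above (1.03), while TEAD kept 1.37, ESRR 1.499 and NKX2 1.09. Repeat bases made up 13.75% of the peak windows and 32.79% of the background windows of equal GC share. With the background also matched on repeat bases, the calls for AP1, RUNX and the TGTCA element were lost (1.07, 1.08 and 1.01) and POU had 1.01. There NKX2 had 1.10 and TEAD 1.29, both lower than before, whereas MEF2 had 1.63. The shuffled forms were not searched against that background. Within 50 bp of the summit, the calls for MEF2 (1.01), AP1 (1.05), SOX (1.03) and POU (0.985) were lost and the T-box had 1.04. The CTCF ratio, which rests on 36 peaks and 91 background windows, was 0.174 within 50 bp, 0.677 within 250 bp and 0.6001 against flanking windows. In each replicate alone the call for SOX was lost (1.03, adjusted exact p of 0.066 for replicate 1 and 0.0712 for replicate 2), and in replicate 2 alone so was that for the T-box (0.979, adjusted exact p = 0.641).

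**Figure D4:**
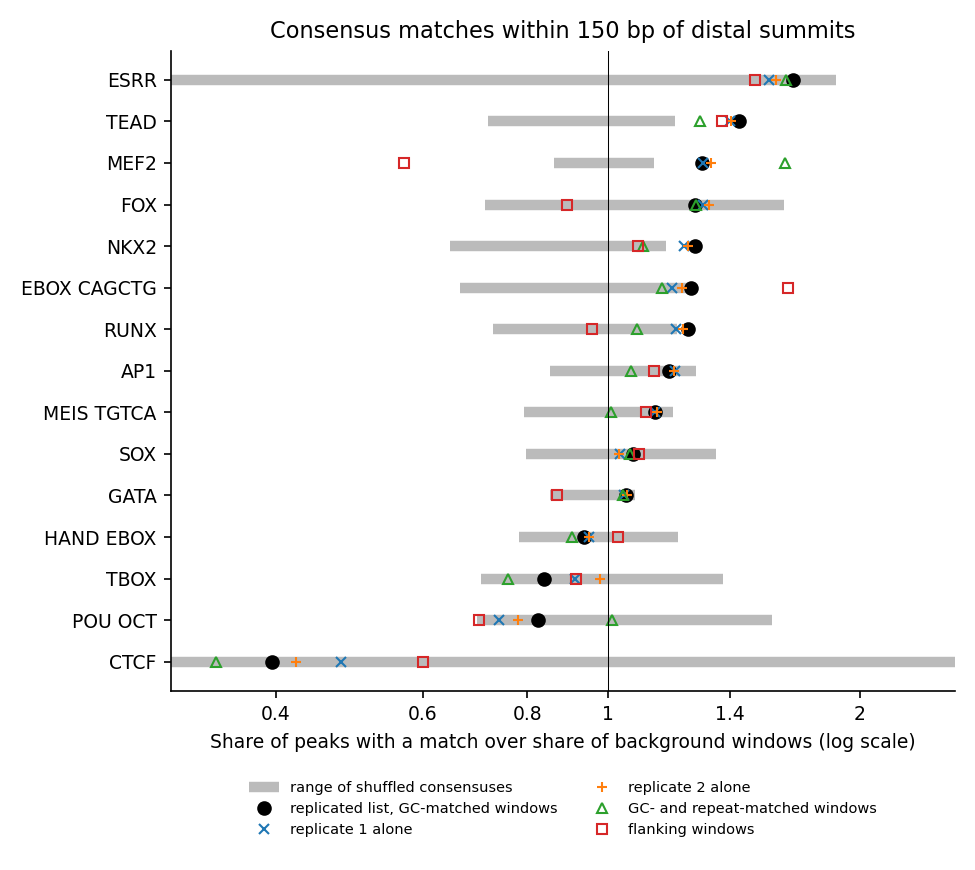
Ratio of the share of distal peaks with a consensus match to that of background windows (horizontal axis, log scale) for the 15 sequences called, in the replicated list, in each replicate alone and against other backgrounds; grey bars give the range of shuffled consensuses, clipped at the edges of the axis for ESRR and CTCF. TEAD has 1.43 and its shuffled forms reach 1.204; MEF2 has 1.297 against windows of equal GC share and 0.570 against flanking windows.

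Chromosome X carried far fewer H3K27ac peaks than any autosome. It held 6.57 replicated peaks per Mb outside assembly gaps, against 27.2 ± 5.03 (SD, 19 autosomes) on the autosomes, a ratio of 0.242 (0.215 in replicate 1 and 0.2498 in replicate 2). The autosomes ranged from 20.2 on chromosome 14, where Myh6 and Myh7 lie, to 41.6 on chromosome 11. Of the X-linked protein-coding genes 35.6% had a start peak, against a mean of 54.2% over the autosomes and a lowest autosome of 43.6%. The X-linked housekeeping genes Hprt (15.9) and Pgk1 (14.1), singled out after their values were seen, had start peaks. Per protein-coding gene, X had 1.13 peaks and the autosomes 3.22 ± 0.580 (SD), a ratio of 0.352. No test was made, since X is a single chromosome, and the embryos were pooled over both sexes.

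**Figure D5:**
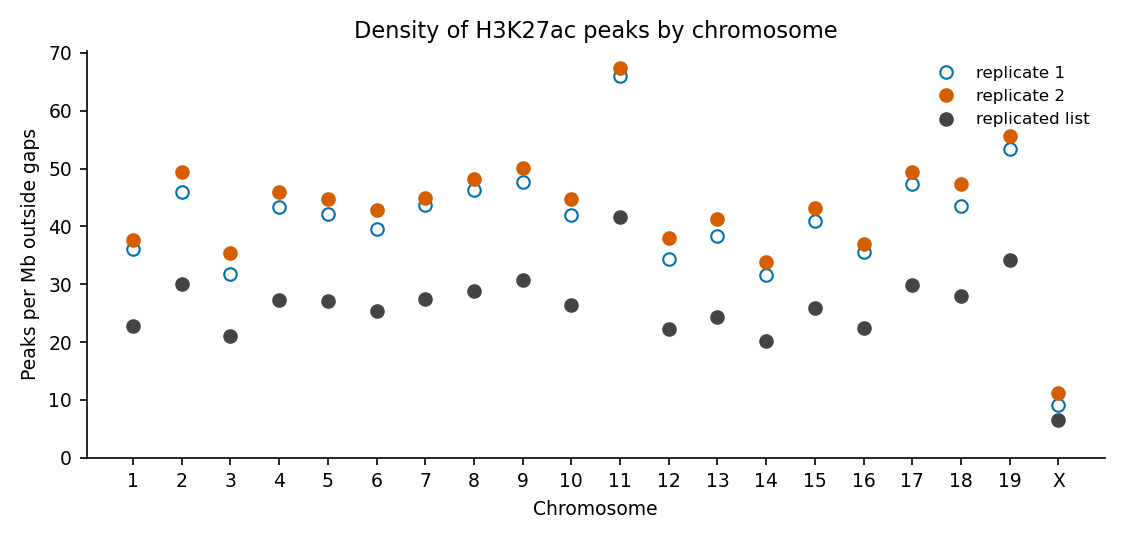
Peaks per Mb outside assembly gaps (vertical axis) on each autosome and on X (horizontal axis), as points for the replicated list and for each replicate alone. Chromosome X has 6.57 replicated peaks per Mb, the lowest autosome (chromosome 14) 20.2 and the highest (chromosome 11) 41.6.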

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

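The alternatives with a repeat-matched background, the erythroid list without globins, bases away from starts of other genes, X peaks per gene, and the 500 and 1000 longest clusters were chosen after the data were seen. Of 100 recomputed answers to the comparisons, 70 stayed within the limits set and 30 moved. Most of these answers are shares or counts, which have no direction to turn. Of 515 recomputed values of single lists and sequences, 456 kept their side of the threshold, 37 lost the call, 11 gained it and 11 reversed. Reversed means a turned direction with a call in at least 1 of the 2 settings. Values called in neither setting were counted as kept even where their direction turned. An example is the second heart field list in a window of 100 kb (4.81 kb, random lists 5.16 kb). With at least 50% of a peak covered, the overlap was 57.1% for replicate 1 and 42.1% for replicate 2, with 98.1% and 90.7% in the strongest 10%, 33.8% and 20.8% in the weakest, and 70.3% of the 10000 strongest of replicate 2 among those of replicate 1. With reciprocal 50% it was 37.6% and 35.4%, with 84.5% and 87.3% in the strongest 10%, 16.1% and 14.4% in the weakest, and 67.5% of the 10000 strongest in each direction. With q up to 0.01 the weakest 10% of replicate 1 had 57.3% and that of replicate 2 had 32.3%. The share of pooled peaks meeting an overlap rule in both replicates was 45.2% (1 bp), 29.6% (50% of the pooled peak), 43.0% (50% of the single-replicate peak), 44.4% (50% of either) and 28.4% (reciprocal 50%), against 52.9% in the replicated list.

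Lists with more covered bases fell from 9 to 5 in a window of 100 kb. With distal peaks only they were 6, and with members with a start peak only 5 of the 9 passed, along with skeletal muscle. Those with fewer went from 3 to 0 in a window of 20 kb and with distal peaks only, where all 3 medians were 0.0 kb, the lowest possible value, and to 1 with bases away from other starts. With members with a start peak only the count was 0 because these 3 lists had too few such members to be run. Without replicate 1 the epithelial call was lost (0.467 kb, adjusted permutation p = 0.0556). Skeletal muscle reversed to 21.5 kb among its 4 members with a start peak (adjusted permutation p = 0.0054). Of these 4, Tnni2 (30.96 kb) and Tnnt3 (53.19 kb) lie near each other on chromosome 7, so their windows share bases. Lists more often near a long cluster numbered 4 to 5 when a replicate was left out, 6 with start peaks kept (working myocardium, endocardium and housekeeping added), and 2 when ranked by summed fold times width, where the sarcomere call was lost. The X ratio was 0.215 to 0.2498 when a replicate was left out and 0.352 per gene. Against flanking windows GATA (0.868), MEF2 (0.570) and FOX (0.893) reversed to fewer, and the CATCTG E-box (1.03) and SP_KLF (1.77) to more. The RUNX ratio (0.956) also crossed 1 but did not pass there (adjusted exact p = 0.2435). Within 50 bp the T-box (1.04) and ETS (0.684) reversed, within 250 bp SP_KLF (1.25), and with repeat matching POU (1.01). Of these, the T-box and POU ratios crossed 1 without passing the test in that setting. Calls were lost within 50 bp for MEF2 (1.01), AP1 (1.05), SOX (1.03) and POU (0.985), for the T-box against flanks (0.915) and without replicate 1 (0.979), and for SOX without either replicate (1.03 each). NFI was called in each replicate alone (4.25 and 4.14), with matches in 0.0479% and 0.0442% of the peaks. Apart from the base composition tested for MEF2, the causes of these changes were not tested. No paired analysis was possible because the labels pair no samples, and the shuffled sequences were a control rather than an alternative. The unknown depth limits all statements on weak peaks, and no value here tells a missing mark from too few reads.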

Other observations

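The tests of peaks per gene on X, of X peaks of fold 6 or more, of the width of start peaks and of the rise of motifs other than MEF2, and the number of shuffled sequences behind the MEF2 rise, were chosen only after results were seen. The widest start peaks of embryonic heart lay at genes outside and inside the cardiac lists. Unc5b, a receptor of netrins, had one of 23.8 kb (10:60804951-60828793), followed by Mical2, an oxidase of actin (17.9 kb), Smad7, an inhibitor of TGF-beta signalling (15.04 kb), Mef2d, a muscle transcription factor (14.7 kb), Myh7 (14.3 kb), Zmynd8, a reader of chromatin marks (11.01 kb), Myh6 (10.3 kb) and the homeobox gene Meis2 (9.96 kb).

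Broad start peaks were a feature of the cardiac lists. Among members with a start peak, the strongest one had a median width of 4.09 kb in the cardiac transcription factors and 3.71 kb in the sarcomere list, where random lists of genes with a start peak had about 1.03 and 1.02 kb. Of these members, 15 of 24 factors and 13 of 22 sarcomere genes were among the widest 5% of start peaks (above 3.42 kb). Medians were also larger for calcium handling and ion channels (2.52 kb), working myocardium (2.23 kb), muscle energy metabolism (2.27 kb) and the second heart field (2.24 kb), with adjusted permutation p of 0.00085 for the first 4 lists, 0.00136 and 0.00737. The housekeeping list (1.54 kb, adjusted permutation p = 0.101) and the endocardial list (1.35 kb, 0.326) did not pass, nor did the other 9 of the 17 lists tested.

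Chromosome X had 6.57 peaks per Mb, below each of the 19 autosomes. The lower number of genes on X was excluded as the whole cause, since X had 1.13 peaks per protein-coding gene and the lowest autosome 1.92. Repeats marked in the genome sequence were excluded as the whole cause as well, since X had 12.3 peaks per Mb outside them and the lowest autosome 30.9. Whether reads can be placed was not measured, so other sequence in which they cannot be placed stays open. Folds on X at 0.5 times those of the autosomes, together with fewer genes, stay open. X had 1.10 peaks of fold 3 or more per gene, within the 0.590 to 1.39 of the autosomes for fold 6 or more (mean 0.951). Its 0.439 peaks of fold 6 or more per gene (95% Poisson interval 0.398 to 0.483) lay above the 0.185 to 0.406 of the autosomes for fold 12 or more (mean 0.281), with an interval that reached into that range. The factor of 0.5 was set for the test. Both sexes were pooled and the scaling of the control is unknown, so the factor that 1 active copy per cell would give is not known here. No biological explanation was tested, because the design has 1 group of pooled sexes.

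The weakest 10% of replicate 1 peaks was overlapped by replicate 2 in 44.7% of cases, far above the 3.92% of random placement of the whole list. Placing each peak anew within 5 kb of its position gave 20.6% (at most 21.6% in 100 placements), 0.460 times the observed share. Lying in the same stretch of 5 kb thus did not account for the whole overlap. Closeness to strong regions at a finer scale stays open, since moves of up to 5 kb break it too. Of the overlapped weak peaks, 56.6% lay on a replicate 2 peak above the median fold of that list. Whether weak peaks are pieces of broader replicate 2 peaks stays open, since 40.2% of the overlapped ones lay on a peak at least 2 times as wide, between the bounds of 25% and 50% set beforehand. No biological explanation was tested, as there is a single group.

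MEF2 matches were fewer in distal peaks than in flanking windows (0.570) but more than in windows of equal GC share (1.297); base composition may account for the former, since shuffled MEF2 sequences had a median ratio of 0.370 against the flanks (0.311 to 0.415). MEF2 matches were 5.31 times as frequent 150 to 250 bp from the summit as within 50 bp, and 2 of 100 shuffled sequences rose as much (median 3.6, highest 6.27), so base composition and a true position beside the summit cannot be told apart. A first draw of 20 shuffles and another disagreed on whether any rose as much, so the number was raised to 100, and the bound for an open outcome was set at under 5 of 100 after that. Of the 11 sequences with more matches, AP1 (1.44 times, 1 of 100 shuffles as high) and TEAD (1.31, 4 of 100) also rose under that bound, unadjusted for 11 tests, GATA did not (1.53, 6 of 100), and RUNX had 0.999, with 1 of 100 shuffles as low. No biological explanation was tested, since the design has 1 group.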
